A study of Homo sapiens with 6 samples.

How the data were processed

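Poly(A) RNA sequencing of 6 libraries was analysed, 2 each from H9 human embryonic stem cells (hESC), neuroepithelial progenitors (NEP) and mesendoderm cells (ME). Per the labels' protocols, hESC and NEP were grown on mitomycin-treated mouse embryonic fibroblasts, RNA was extracted with Trizol, and libraries were made with a NEBNext Ultra RNA kit, which is not stated to be stranded. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name HISAT2, DESeq2 and the genome build GRCh38 (hg38), without versions, and give DESeq2 no role. The counter and the annotation release are not given in the sources used here.

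The deposited table of all genes held an estimated count per gene and library, as its column names and values showed: 12.2 to 13.5% of a library's values, those of 0 included, were not whole, and library totals differed. The same deposited table held FPKM values made by the authors, scaled by gene length and library total per the file headers. The authors' deposited comparison tables held group means in FPKM, a log2 ratio of those means, and a p-value with its adjusted value, per the file headers. These tables listed genes with an absolute log2 ratio above 1 and an adjusted p under 0.05, as tested on the tables. A further 16 per-sample columns of these tables were not used. Of 20289 genes, 583 had no symbol, and 575 of these were named from GENCODE release 29, which also gave gene positions, biotypes and transcript lengths. It held 20171 of the identifiers, 19783 of them as protein-coding.

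Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, robust, two-sided). TMM scaling factors and the filterByExpr filter were used, and all 6 libraries entered 1 fit with a mean per group, so that the groups shared an estimate of the spread (3 residual degrees of freedom, median prior degrees of freedom 21.1, common biological coefficient of variation 3.78%). Of the genes, 14710 were tested. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and counted also at an absolute log2 fold change of at least 1. All adjusted p values of genes come from this fit unless another tool is named. "Rose", "fell", "up" and "down" of genes refer to called genes.

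Gene lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation. As an alternative, the fry p-value tested whether a list's genes move, on balance, one way, and its mixed p-value whether they change in either direction; neither compares the list with other genes. The 41 lists covered pluripotency, neural and other lineages, fibroblast feeder and blood cells, signalling pathways, metabolism, stress, cell cycle, ribosome biogenesis, RNA modification, chromatin and interferon genes. Lists, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule named NAT10, its cofactor THUMPD1, NR2F1 and NR2F2; in each comparison the 6 largest rises and 6 largest falls among called protein-coding genes with at least 10 CPM in the higher group and no overlap between libraries; from each list up to 3 members with the largest change in the list's main direction and up to 1 the other way, with at least 1 CPM in the higher group; and POU5F1, NANOG, SOX2, PAX6, SOX1, TBXT, MIXL1, EOMES and SOX17. Other genes in the text were chosen after their values were seen: 8 of the genes that moved in opposite directions, the low anterior and endoderm markers, the keratins and squamous markers, and COL1A2. KEGG and gene ontology terms of 10 to 500 genes were tested with a hypergeometric test among tested genes that carry an annotation, with Benjamini-Hochberg adjustment.

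A fold against a group with 0 counts was given as a lower bound, against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of library-scaled counts was given with an exact 95% interval for counting error. Some 252 tested genes had a group with 0 counts. A floor of 3 counts in a library was 0.130 to 0.154 CPM. The 2 libraries of each group differed by more than counting error over genes with at least 20 counts (chi-square per degree of freedom 5.29 in hESC, 2.29 in NEP and 1.93 in ME), so none were taken for repeated sequencing of 1 library, and all 6 were counted as the labels number them. This does not exclude separate preparations of 1 RNA, and 80 genes made up 42.4% of the hESC sum. Because both comparisons share the hESC libraries, 20 simulations of unchanged groups were made. They drew NEP and ME around the observed hESC means, so they leave out the error that the shared libraries add to both comparisons. Genes that share reads with near-identical copies, such as ribosomal protein genes with their pseudogenes, histones and keratins, are uncertain where the counting could split them, and so are overlapping and antisense genes, since no strand is stated.

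The procedure was tested on simulated data for the 14710 tested genes with 200 changed genes per comparison. For NEP against hESC it recovered 48 of 64 genes changed by 0.5 on the log2 scale, 63 of 70 changed by 1 and 65 of 66 changed by 2, with 29 unchanged genes called. For ME against hESC it recovered 41 of 66, 55 of 65 and 67 of 69, with 14 unchanged genes called, and for NEP against ME 44 of 63, 68 of 84 and 49 of 53, with 10. The share of unchanged genes among the calls was thus above the nominal 5% in all 3 comparisons, most in NEP against hESC. The simulation was not repeated, so a small excess over 5% may be chance. Its 200 changed genes were far fewer than the 11470, 9326 and 10244 genes called in the data. It therefore does not give the share of unchanged genes among the real calls. A glycolysis list shifted in the simulation was called in all 3 comparisons, also with an estimated correlation (camera adjusted p = 0.00202, 0.00171 and 0.00514), and 0 other lists were called, the HIF list being left out because it shares genes with the shifted list. The genes were drawn independently, so the simulation cannot show how often lists of correlated genes are called without a change.

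The alternatives were DESeq2 size factors, upper-quartile scaling, library size alone, no filter, a stricter filter (10 counts in every library of a group and a mean of 1 CPM), DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the 4 libraries of a comparison alone, the replicate number as a block, each library left out in turn, and a test against a 2-fold change. A further alternative, without genes whose transcripts are under 1000 bases, was chosen after seeing the data. A change of direction was counted as reversed where the main or the alternative result was called. Under the other scalings the median log2 fold change of all genes was furthest from 0 with upper-quartile scaling in NEP against hESC, at -0.0647. Genes linked to the sex chromosomes were not reported by library, and some genes that the rule would name are not reported here.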

Results

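Poly(A) RNA was sequenced from H9 human embryonic stem cells (hESC, an established pluripotent line), from neuroepithelial progenitors (NEP) and from mesendoderm cells (ME) made from them. NEP were differentiated for 6 days with 3 µM CHIR99021 (an activator of WNT signalling through GSK3 inhibition), 2 µM DMH1 (a BMP receptor inhibitor) and 2 µM SB431542 (an inhibitor of the TGF-beta, activin and NODAL receptors). ME were differentiated for 36 h with 5 µM CHIR99021. Each of the 3 groups had 2 libraries. The libraries held 22189247 and 23230944 counts in hESC, 19318623 and 19559133 in NEP, and 21935723 and 21925859 in ME. Levels are given in CPM (counts scaled to a common library total), as the mean ± SD over the 2 libraries of a group (n = 2). Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Counting intervals are at 95%, and these intervals and the floor of 3 counts over a group cover counting error only.

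The series concerns NAT10, the acetyltransferase that writes N4-acetylcytidine (ac4C) in RNA, and the orphan nuclear receptor NR2F1 in neuroectoderm specification. NAT10 (ENSG00000135372, chromosome 11, 34105602 to 34147670 in GRCh38, a protein-coding gene) stood at 127 ± 4.16 CPM in hESC, 116 ± 2.78 in NEP and 143 ± 1.78 in ME. It was lower in NEP than in hESC (log2 fold change -0.12, SE 0.0421, edgeR adjusted p = 0.0104) and higher in ME than in hESC (log2 fold change 0.18, SE 0.0411, edgeR adjusted p = 6e-04). The direct difference between NEP and ME was the largest of the 3 for NAT10 (log2 fold change -0.30, SE 0.0418, edgeR adjusted p = 7.03e-07). THUMPD1, the RNA-binding cofactor of NAT10 on transfer RNA, also fell in NEP, from 96.0 ± 2.29 to 77.3 ± 0.241 CPM (log2 fold change -0.31, SE 0.0511, edgeR adjusted p = 5.33e-06). In ME it stood at 96.3 ± 6.59 CPM (log2 fold change 0.01, SE 0.0495, edgeR adjusted p = 0.941). The small fall of NAT10 in NEP kept its direction but lost its call without hESC replicate 1 (log2 fold change -0.09, edgeR adjusted p = 0.0852) and without NEP replicate 2 (log2 fold change -0.10, edgeR adjusted p = 0.108). The limma adjusted p was 0.207 on log2(FPKM + 1) and 0.209 on log2(FPKM + 0.1). Over the 18 alternatives its log2 fold change ran from -0.19 to -0.07 and its adjusted p from 0.000169 to 1, the last in a test against a 2-fold change, which changes as small as those of NAT10 could not pass in any comparison.

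NR2F1 (ENSG00000175745, chromosome 5, 93583224 to 93594615 in GRCh38, a protein-coding gene) was all but confined to NEP among the 6 libraries. Its level was 20.9 ± 2.25 CPM in NEP against 0.0892 ± 0.00333 in hESC (log2 fold change 7.78, SE 0.307, edgeR adjusted p = 1.3e-17), with 817 counts against 4. In ME 3 counts were seen over the 2 libraries, and the ratio of NEP to ME was 306 (counting interval 105 to 1490), with edgeR adjusted p = 2.54e-17. ME and hESC were not told apart at these counts (edgeR adjusted p = 0.782). Its paralogue NR2F2 rose to 15.4 ± 1.57 CPM in NEP from 0.226 ± 0.135 in hESC (log2 fold change 6.07, SE 0.291, edgeR adjusted p = 7.8e-16). In the authors' deposited table of NEP against hESC, NR2F1 had a log2 fold change of 7.87 and NR2F2 of 4.60.

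**Figure D1:**
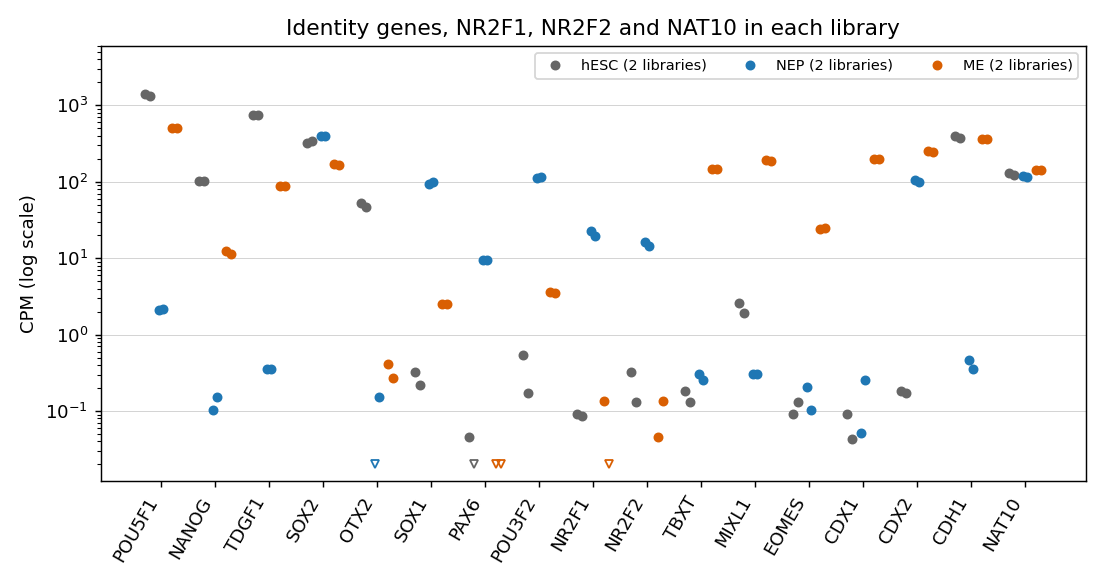
Levels of 17 genes in each library, in CPM on a log scale, with 2 libraries per group (grey, hESC; blue, NEP; orange, ME); each point is a library and an open triangle at the lower edge is a library with 0 counts. NR2F1 and PAX6 stand highest in NEP, TBXT and MIXL1 in ME, and NAT10 lies between 114 and 145 CPM in all 6 libraries.

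The comparison of NEP with hESC asked what changed over neural induction. Pluripotency factors were lost: POU5F1, the core pluripotency transcription factor, fell from 1371 ± 49.7 to 2.12 ± 0.0236 CPM (log2 fold change -9.33, SE 0.0618, edgeR adjusted p = 3.45e-33), and NANOG fell from 102 ± 1.61 to 0.128 ± 0.0354 CPM (log2 fold change -9.58, SE 0.152, edgeR adjusted p = 5.78e-26). Neuroepithelial transcription factors rose, among them SOX1, the early neural plate factor, from 0.269 ± 0.0731 to 96.0 ± 3.15 CPM (log2 fold change 8.46, SE 0.140, edgeR adjusted p = 1.33e-25), and POU3F2, from 0.362 ± 0.266 to 114 ± 2.80 CPM. SOX2, shared by pluripotent and neural cells, rose slightly, from 332 ± 14.9 to 397 ± 4.84 CPM (log2 fold change 0.26, SE 0.0372, edgeR adjusted p = 7.47e-07). The tested HOX genes of groups 1 to 9 rose from near 0, led by HOXB9, from 0.224 ± 0.0714 to 690.3 ± 26.9 CPM (log2 fold change 11.56, SE 0.0941, edgeR adjusted p = 7.09e-32). Epithelial adhesion genes fell, CDH1 (E-cadherin) from 382 ± 15.4 to 0.409 ± 0.0747 CPM (log2 fold change -9.85, SE 0.0897, edgeR adjusted p = 8.05e-31). In all, 5718 genes rose and 5752 fell of 14710 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 1905 rose and 2589 fell by at least 2-fold.

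List counts are out of the members tested, which leaves out genes with too few counts or outside the table, as in the naive pluripotency (9 of 14 tested), anterior neural (7 of 18) and histone lists (10 of 48). The 48 entries of the histone list also count older symbols, such as HIST1H1B, of genes that it holds under newer names. Among core pluripotency genes 22 fell and 1 rose of 23 (camera adjusted p = 2.57e-11, adjusted p = 0.137 with an estimated correlation), SOX2 being the member that rose. TDGF1, a NODAL co-receptor, fell from 747 ± 2.54 to 0.358 ± 0.00212 CPM, and PRDM14, a germ-cell and pluripotency regulator, had 3 counts left in NEP, a ratio of hESC to NEP of 1028 (counting interval 351 to 4990). Of the naive pluripotency genes 9 fell and 0 rose of 9 (camera adjusted p = 0.00149, adjusted p = 0.207 with an estimated correlation), including TFCP2L1 and TFAP2C. FGF4, a growth factor of pluripotent cells, went from 10.8 ± 1.76 CPM to 0 counts (at least 141-fold lower). KLKB1, plasma kallikrein, went from 22.9 ± 0.0980 CPM to 0 counts (at least 299-fold lower), and NLRP12, a cytosolic sensor of the NLR family, was at least 136-fold lower with 0 counts in NEP.

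Of the neuroepithelium genes 26 rose and 5 fell of 34 (camera adjusted p = 2.58e-05, adjusted p = 0.137 with an estimated correlation). PAX6, a neural and eye field regulator, had 1 count in hESC and 9.50 ± 0.0563 CPM in NEP, a ratio of 426 (counting interval 76 to 16900), with edgeR adjusted p = 4.98e-14. Against the list's name, OTX2, a forebrain and midbrain factor that hESC also express, fell from 49.6 ± 3.62 CPM to 3 counts, a ratio of 647 (counting interval 221 to 3140). Of the anterior neural genes 5 fell and 2 rose of 7 (camera adjusted p = 0.236). FEZF1, a forebrain factor, fell from 84.0 ± 1.91 to 0.204 ± 0.0735 CPM, and PAX2, of the midbrain-hindbrain boundary and kidney, rose at least 146-fold from 0 counts in hESC. Of the hindbrain and HOX genes 27 rose and 2 fell of 29 (camera adjusted p = 1.31e-09, adjusted p = 0.137 with an estimated correlation). HOXB8 (at least 672-fold higher, 45.0 ± 1.31 CPM), HOXB4 (at least 639-fold), HOXA2 (at least 232-fold) and HOXB7 (at least 181-fold) all had 0 counts in hESC. The list's median log2 fold change was 8.51, or 6.76 with genes at 0 counts set to their bound. URAD, a uric acid pathway enzyme, also rose at least 211-fold from 0 counts. Neural crest and placode genes were divided (11 rose and 5 fell of 20, camera adjusted p = 0.236). PAX3, a dorsal neural tube and crest factor, rose to 9.12 ± 0.632 CPM from 2 counts, while FOXD3, expressed in both crest and stem cells, fell from 7.11 ± 2.06 CPM to 0 counts (at least 92.2-fold lower). Of the neuron genes 9 rose and 6 fell of 18 (camera adjusted p = 0.263). NEUROG2, a proneural factor, rose to 17.0 ± 3.03 CPM from 2 counts, and GAP43 fell from 28.3 ± 0.330 to 10.1 ± 0.482 CPM.

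Markers of other lineages did not follow a common direction. TBXT, the primitive streak factor, was at 0.157 ± 0.0374 CPM in hESC and 0.281 ± 0.0378 in NEP (edgeR adjusted p = 0.25), and EOMES at 0.111 ± 0.0274 and 0.153 ± 0.0731 (edgeR adjusted p = 0.633), whereas MIXL1 fell from 2.26 ± 0.494 to 0.306 ± 0.00182 CPM. Of the mesendoderm genes 10 rose and 6 fell of 26 (camera adjusted p = 0.354). CDX2, a posterior axis factor, rose from 0.178 ± 0.00666 to 102 ± 2.27 CPM. Of the paraxial mesoderm genes 12 rose and 5 fell of 19 (camera adjusted p = 0.0481, adjusted p = 0.313 with an estimated correlation), among them HOXB1, which rose to 50.5 ± 1.49 CPM, and MEOX1. That call was lost with library-size scaling (camera adjusted p = 0.0626), without hESC replicate 1 (0.0644), NEP replicate 2 (0.0718), ME replicate 1 (0.0541) and ME replicate 2 (0.0544). Of the definitive endoderm genes 9 fell and 3 rose of 16 (camera adjusted p = 0.0706), and without NEP replicate 2 the adjusted p was 0.043. The lateral and cardiac mesoderm list had 4 down and 2 up of 12 (camera adjusted p = 0.359), with KDR, a VEGF receptor, going from 164 ± 7.21 to 0.205 ± 0.146 CPM. The amnion and trophoblast list had 5 down and 1 up of 10 (camera adjusted p = 0.237). The endothelial and blood list had 6 down and 0 up of 9 (camera adjusted p = 0.119). Of the surface ectoderm genes 11 fell and 2 rose of 15 (camera adjusted p = 0.000168, adjusted p = 0.313 with an estimated correlation). Fibroblast genes, included because hESC and NEP were grown on mouse embryonic fibroblast feeders, were divided (16 fell and 10 rose of 31, camera adjusted p = 0.428). COL1A1 fell from 486 ± 25.7 to 41.5 ± 4.98 CPM and IGFBP5 rose from 4.64 ± 0.0468 to 156 ± 0.230 CPM.

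Signalling target lists moved in different directions. Of the NODAL and TGF-beta targets 15 fell and 2 rose of 18 (camera adjusted p = 6.28e-05, adjusted p = 0.313 with an estimated correlation). The feedback inhibitors LEFTY1 and LEFTY2 fell from 255 ± 3.81 to 0.102 ± 0.0728 CPM and from 222 ± 1.41 to 0.102 ± 0.000605 CPM. FGF8 rose from 2.73 ± 0.560 to 27.1 ± 1.57 CPM. Of the WNT targets 17 rose and 2 fell of 25 (camera adjusted p = 8.31e-05, adjusted p = 0.141 with an estimated correlation). LEF1, a WNT effector, rose from 0.135 ± 0.0681 to 98.3 ± 1.77 CPM, and MYC fell from 52.8 ± 1.18 to 4.45 ± 0.965 CPM. Of the BMP targets 8 rose and 5 fell of 16 (camera adjusted p = 0.452). ID1, a direct target, fell from 106 ± 12.2 to 4.83 ± 0.859 CPM, and MSX2 rose to 12.7 ± 0.870 CPM. The FGF and ERK targets had 10 up and 7 down of 20 (camera adjusted p = 0.323), with the ERK phosphatase DUSP6 rising to 243 ± 0.970 CPM (log2 fold change 4.75, SE 0.0606, edgeR adjusted p = 6.24e-28). Of the retinoic acid targets 16 rose and 4 fell of 20 (camera adjusted p = 0.00157, adjusted p = 0.313 with an estimated correlation), against which CYP26A1, the enzyme that degrades retinoic acid, fell from 31.1 ± 0.131 CPM to 3 counts. Of the hedgehog genes 9 rose and 2 fell of 11 (camera adjusted p = 0.0048, adjusted p = 0.313 with an estimated correlation). PTCH1, receptor and target, rose from 16.0 ± 0.913 to 242 ± 3.08 CPM. NOTCH genes had 13 up and 7 down of 21 (camera adjusted p = 0.251). The ligand DLL1 rose from 5.57 ± 0.744 to 40.0 ± 1.54 CPM.

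Of the epithelial adhesion genes 25 fell and 1 rose of 26 (camera adjusted p = 9.93e-11, adjusted p = 0.137 with an estimated correlation), the member that rose being DSP (desmoplakin), from 135 ± 4.43 to 403 ± 2.53 CPM. The splicing regulator ESRP1 fell from 224 ± 2.88 to 0.409 ± 0.0747 CPM and the tight junction gene CLDN7 from 94.8 ± 1.83 to 0.102 ± 0.0728 CPM. Of the epithelial to mesenchymal transition genes 11 rose and 3 fell of 15 (camera adjusted p = 0.00499, adjusted p = 0.429 with an estimated correlation), including the repressors of CDH1 transcription ZEB2 (0.608 ± 0.306 to 215 ± 8.15 CPM) and ZEB1 (0.157 ± 0.0374 to 50.1 ± 0.823 CPM). MMP14, a membrane-bound metalloproteinase, went the other way.

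Metabolic and growth lists moved in both directions. Of the glycolysis genes 17 fell and 2 rose of 23 (camera adjusted p = 2.58e-05, adjusted p = 0.364 with an estimated correlation), LDHA (lactate dehydrogenase) from 927 ± 17.2 to 162 ± 3.56 CPM. LDHB rose from 899 ± 0.786 to 1009 ± 7.21. Of the HIF targets 12 fell and 3 rose of 19 (camera adjusted p = 0.0168, adjusted p = 0.313 with an estimated correlation). Of the nuclear respiratory chain genes 24 fell and 2 rose of 36 (camera adjusted p = 0.000974, adjusted p = 0.295 with an estimated correlation). Of the mitochondrially encoded genes 8 fell and 1 rose of 13 (camera adjusted p = 0.00583, adjusted p = 0.439 with an estimated correlation). Mitochondrially encoded genes took 7.08 and 7.40% of the counts of the hESC libraries and 5.13 and 5.26% of those of NEP. Of the unfolded protein response genes 12 fell and 3 rose of 18 (camera adjusted p = 0.0222, adjusted p = 0.364 with an estimated correlation). Of the DNA replication genes 19 rose and 4 fell of 25 (camera adjusted p = 0.00808, adjusted p = 0.313 with an estimated correlation). TYMS rose from 73.5 ± 3.34 to 241 ± 11.5 CPM, and MCM5 fell. Of the ribosomal protein genes 46 rose and 0 fell of 66 (camera adjusted p = 4.98e-09, adjusted p = 0.326 with an estimated correlation), with a median log2 fold change of 0.41, which was 0.37 without hESC replicate 1 and 0.49 without hESC replicate 2, libraries that differed in genes of short transcripts. Of the nucleolar ribosome biogenesis genes 34 fell and 5 rose of 45 (camera adjusted p = 0.000232, adjusted p = 0.207 with an estimated correlation). Of the interferon-stimulated genes 13 fell and 4 rose of 19 (camera adjusted p = 0.00337, adjusted p = 0.295 with an estimated correlation). The sterol synthesis list had 13 down and 2 up of 25 (camera adjusted p = 0.0698), or 0.0415 without hESC replicate 2. The RNA modification enzymes had 19 down and 8 up of 40 (camera adjusted p = 0.202). NSUN2, a writer of 5-methylcytosine, fell from 159 ± 4.34 to 89.9 ± 4.74 CPM, and IGF2BP1, a reader of methylated RNA, rose from 571 ± 13.2 to 1051 ± 42.8. Members went both ways in the lists of amino acid stress (8 rose and 12 fell of 24, camera adjusted p = 0.235) and immediate early genes (10 rose and 12 fell of 24, camera adjusted p = 0.319). They did so too in those of p53 targets (8 rose and 11 fell of 23, camera adjusted p = 0.509), mitosis (11 rose and 12 fell of 25, camera adjusted p = 0.778) and chromatin (11 rose and 8 fell of 22, camera adjusted p = 0.583). The replication-dependent histone genes had 7 down and 0 up of 10 (camera adjusted p = 0.119), in libraries that select for poly(A) tails, which most of these transcripts lack.

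Adjusted over the list alone, the counts in NEP against hESC were the same as over all genes except for BMP targets (9 up), DNA replication (5 down) and ribosome biogenesis (35 down). None of the camera calls of the 3 comparisons held with an estimated correlation. In the chromatin list the median log2 fold change was 0.14, the mean -0.22 and the camera direction up, and in the amnion and trophoblast list camera gave a downward and fry an upward direction. Among KEGG pathways, genes that rose at least 2-fold were enriched for axon guidance (51 of 183, against 21 expected, hypergeometric adjusted p = 1.98e-07) and WNT signalling (34 of 146, adjusted p = 0.00385), and those that fell for neuroactive ligand-receptor interaction (77 of 161, adjusted p = 1.17e-14), which was enriched among genes that rose as well (32 of 161, adjusted p = 0.0405). Among gene ontology terms, anterior/posterior pattern specification led the rise (42 of 85, adjusted p = 2.7e-13). The authors' deposited table for this comparison listed 4275 genes, 1781 up and 2494 down. Of these, 4015 were also called here at 2-fold or more and 0 in the opposite direction, and 479 genes called here at that size were outside the authors' deposited table.

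The comparison of ME with hESC asked what changed over mesendoderm induction. Primitive streak transcription factors rose: TBXT from 0.157 ± 0.0374 to 146 ± 0.147 CPM (log2 fold change 9.81, SE 0.132, edgeR adjusted p = 3.38e-27), MIXL1 from 2.26 ± 0.494 to 190.1 ± 2.03 (log2 fold change 6.40, SE 0.0869, edgeR adjusted p = 4.49e-27) and EOMES from 0.111 ± 0.0274 to 24.7 ± 0.275 (log2 fold change 7.72, SE 0.244, edgeR adjusted p = 2.37e-19). The caudal factors CDX1 and CDX2 rose to 199 ± 1.78 and 247 ± 4.02 CPM, CDX1 from 3 counts, a ratio of 2977 (counting interval 1020 to 14400), and EVX1, a posterior streak factor, rose from 1 count to 68.2 ± 0.713 CPM, a ratio of 3061 (counting interval 549 to 121000). Pluripotency factors fell in part: POU5F1 to 506 ± 1.76 CPM (log2 fold change -1.44, SE 0.0339, edgeR adjusted p = 4.62e-22), NANOG to 11.9 ± 0.584 (log2 fold change -3.10, SE 0.0700, edgeR adjusted p = 1.83e-22) and SOX2 to 168 ± 1.19 (log2 fold change -0.98, SE 0.0385, edgeR adjusted p = 2.42e-17). SOX17, the endoderm factor, had 0 counts in all 6 libraries, a floor of 0.136 CPM in each ME library. In all, 4725 genes rose and 4601 fell of 14710 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 1005 rose and 1506 fell by at least 2-fold.

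Of the mesendoderm genes 17 rose and 5 fell of 26 (camera adjusted p = 1.45e-05, adjusted p = 0.131 with an estimated correlation), with a median log2 fold change of 4.34, or 3.95 with genes at 0 counts set to their bound. CER1, a secreted NODAL and BMP inhibitor, fell from 22.5 ± 2.42 to 1.23 ± 0.257 CPM against the list's name. Definitive endoderm genes were divided (7 rose and 9 fell of 16, camera adjusted p = 0.431). GATA4 rose from 3 counts to 3.58 ± 0.00204 CPM. The paraxial mesoderm list had 11 up and 5 down of 19 (camera adjusted p = 0.0554), which passed the threshold with DESeq2 size factors (0.039) and without hESC replicate 2 (0.0499). The lateral and cardiac mesoderm list had 5 up and 5 down of 12 (camera adjusted p = 0.9). The amnion and trophoblast list had 4 up and 5 down of 10 (camera adjusted p = 0.95). The surface ectoderm list had 8 down and 3 up of 15 (camera adjusted p = 0.314). The endothelial and blood list had 6 down and 0 up of 9 (camera adjusted p = 0.0984), or 0.0434 without ME replicate 2. The fibroblast list had 13 up and 13 down of 31 (camera adjusted p = 0.708), or 14 down with DESeq2 size factors. MMP2, a gelatinase, rose from 15.1 ± 2.46 to 504 ± 6.22 CPM. Of the core pluripotency genes 22 fell and 0 rose of 23 (camera adjusted p = 2.82e-13, adjusted p = 0.101 with an estimated correlation). The naive pluripotency list had 7 down and 1 up of 9 (camera adjusted p = 0.131), KLF5 being the member that rose.

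Neural and axial genes moved as well. Of the hindbrain and HOX genes 22 rose and 4 fell of 29 (camera adjusted p = 8.66e-08, adjusted p = 0.101 with an estimated correlation), among them HOXB8 (at least 189-fold higher) and HOXB4 (at least 165-fold higher), both at 0 counts in hESC, and with IRX2 falling. The list's median log2 fold change was 6.26, or 5.86 with genes at 0 counts set to their bound. SOX1 rose from 0.269 ± 0.0731 to 2.52 ± 0.0307 CPM (log2 fold change 3.21, SE 0.296, edgeR adjusted p = 8.29e-10), PAX6 had 0 counts in ME and 1 in hESC, and the neuroepithelium list had 18 up and 11 down of 34 (camera adjusted p = 0.115). ZIC1, a dorsal neural and paraxial factor, rose from 3 counts to 66.4 ± 3.43 CPM. OTX2 fell to 0.340 ± 0.0965 CPM, TTYH1, a membrane protein of neural stem cells, from 23.4 ± 2.01 to 0.295 ± 0.0964 CPM, and ACTA1, skeletal muscle actin, from 93.4 ± 8.81 to 1.25 ± 0.0314 CPM. The anterior neural list had 4 down and 2 up of 7 (camera adjusted p = 0.286) and the neuron list 5 up and 4 down of 18 (camera adjusted p = 0.451). In the neural crest and placode list 13 rose and 5 fell of 20 (camera adjusted p = 0.0984). MSX1 rose from 0.157 ± 0.0374 to 165 ± 3.21 CPM and DLX5, a placode and limb factor, at least 160-fold from 0 counts.

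Of the WNT targets 21 rose and 1 fell of 25 (camera adjusted p = 2.82e-13, adjusted p = 0.101 with an estimated correlation). DKK4, a WNT antagonist, rose at least 133-fold from 0 counts, and MYC, a target in other cells, fell to 4.42 ± 0.805 CPM. Of the NODAL and TGF-beta targets 12 fell and 3 rose of 18 (camera adjusted p = 0.00619, adjusted p = 0.464 with an estimated correlation). LEFTY1 fell to 1.36 ± 0.128 CPM and LEFTY2 to 1.81 ± 0.386, against which EOMES rose. Of the retinoic acid targets 12 rose and 4 fell of 20 (camera adjusted p = 0.00578, adjusted p = 0.327 with an estimated correlation). CYP26A1 fell to 0.114 ± 0.0322 CPM. The BMP list had 8 up and 4 down of 16 (camera adjusted p = 0.15). ID2 rose from 17.4 ± 0.0793 to 181 ± 7.28 CPM. The FGF and ERK list had 12 up and 5 down of 20 (camera adjusted p = 0.0984). The NOTCH list had 9 up and 9 down of 21 (camera adjusted p = 0.9), or 10 down with DESeq2 size factors. The hedgehog list had 6 up and 5 down of 11 (camera adjusted p = 0.431). Of the epithelial to mesenchymal transition genes 12 rose and 2 fell of 15 (camera adjusted p = 5.84e-05, adjusted p = 0.382 with an estimated correlation). ZEB2 rose to 144 ± 1.62 CPM. Fibronectin (FN1) fell from 334 ± 24.7 to 191 ± 4.54 CPM. Of the epithelial adhesion genes 20 fell and 3 rose of 26 (camera adjusted p = 0.00578, adjusted p = 0.327 with an estimated correlation), AP1M2, a sorting adaptor of epithelial cells, from 119 ± 2.43 to 35.2 ± 1.55 CPM. DSP rose to 1338 ± 11.6 CPM.

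Of the p53 targets 18 rose and 2 fell of 23 (camera adjusted p = 0.000319, adjusted p = 0.305 with an estimated correlation). The cell cycle inhibitor CDKN1A rose from 41.5 ± 4.23 to 189 ± 0.791 CPM, and the apoptosis gene BBC3 fell from 9.64 ± 0.744 to 6.15 ± 0.0928. Of the DNA replication genes 20 rose and 0 fell of 25 (camera adjusted p = 3.47e-06, adjusted p = 0.284 with an estimated correlation). Of the sterol synthesis genes 16 fell and 1 rose of 25 (camera adjusted p = 5.1e-05, adjusted p = 0.305 with an estimated correlation), SC5D, a late enzyme of the pathway, from 568 ± 12.4 to 113 ± 0.738 CPM. Of the nucleolar ribosome biogenesis genes 25 fell and 5 rose of 45 (camera adjusted p = 0.00619, adjusted p = 0.305 with an estimated correlation), DDX21, a nucleolar helicase, from 505 ± 0.755 to 346 ± 7.18 CPM, with UTP14A the other way. The ribosomal protein list had 26 up and 1 down of 66 (camera adjusted p = 0.0984). Without hESC replicate 1 it had 22 up and 24 down (camera adjusted p = 0.772) and without hESC replicate 2 44 up and 1 down (4.28e-06), and with library-size scaling the adjusted p was 0.0483, so its direction depended on which hESC library was kept, and these libraries differed in genes of short transcripts. The mitochondrially encoded list had 5 down and 1 up of 13 (camera adjusted p = 0.126), or 10 down and 0.00474 without hESC replicate 1. The glycolysis list had 13 up and 6 down of 23 (camera adjusted p = 0.137). PDK1, a kinase that limits pyruvate oxidation, rose from 109.6 ± 2.95 to 246 ± 5.43 CPM. The HIF list had 9 up and 4 down of 19 (camera adjusted p = 0.383). The interferon list had 9 down and 5 up of 19 (camera adjusted p = 0.0984). The RNA modification list had 14 down and 10 up of 40 (camera adjusted p = 0.538), or 10 down with library-size scaling. METTL3, the main writer of N6-methyladenosine, fell from 100.3 ± 3.80 to 59.2 ± 1.41 CPM. Lists with calls both ways were nuclear respiratory chain (9 rose and 7 fell of 36, camera adjusted p = 0.855, or 9 and 9 with DESeq2 size factors, 9 and 12 without hESC replicate 1, and 11 and 7 without hESC replicate 2), immediate early genes (9 rose and 9 fell of 24, camera adjusted p = 0.538, or 9 and 10) and mitosis (9 rose and 9 fell of 25, camera adjusted p = 0.807, or 8 and 9, and 9 and 7 with library-size scaling). Calls also went both ways in amino acid stress (6 rose and 11 fell of 24, camera adjusted p = 0.383), unfolded protein response (3 rose and 1 fell of 18, camera adjusted p = 0.657) and chromatin (11 rose and 7 fell of 22, camera adjusted p = 0.613). Of the replication-dependent histone genes 1 fell and 0 rose of 10 (camera adjusted p = 0.9).

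Adjusted over the list alone, the counts in ME against hESC were the same as over all genes except for fibroblast (14 down), endothelial (7 down), NOTCH (10 down), nuclear respiratory chain (6 down), unfolded protein response (2 up and 0 down), histone (0 down) and ribosomal protein genes (24 up). Medians and means of the log2 fold change differed in sign in the lists of chromatin (0.11 and -0.18), lateral and cardiac mesoderm (-0.07 and 0.76), amnion and trophoblast (-0.63 and 1.32), surface ectoderm (-0.12 and 0.69), fibroblast (-0.08 and 0.11) and histone genes (0.20 and -0.01). For NOTCH genes both were negative (-0.09 and -0.33) and the camera direction was up, the median being 0.03 with genes at 0 counts set to their bound. Genes that rose at least 2-fold were enriched for the KEGG pathways of pluripotency signalling (29 of 128, hypergeometric adjusted p = 3.34e-07) and axon guidance (35 of 183, adjusted p = 3.6e-07). Those that fell were enriched for neuroactive ligand-receptor interaction (61 of 161, adjusted p = 6.41e-18), and also for pluripotency signalling (28 of 128, adjusted p = 0.00252). The authors' deposited table for ME listed 2270 genes, 940 up and 1330 down, of which 2126 were also called here at 2-fold or more. Among the listed genes tested here, 1 had a fitted change of the opposite sign, counted whether or not it was called.

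**Figure D2:**
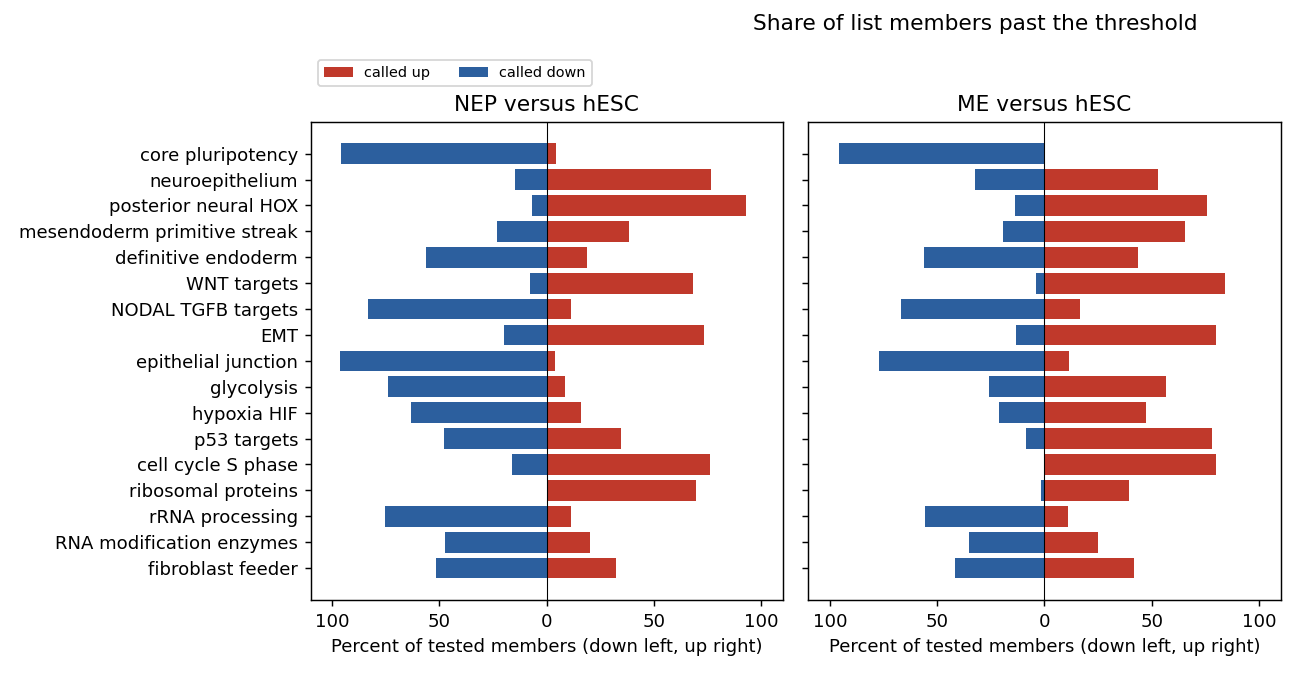
Percent of the tested members of 17 gene lists that were called up (red, right of 0) or down (blue, left of 0) in NEP against hESC and in ME against hESC, with 2 libraries per group and edgeR adjusted p under 0.05. Core pluripotency genes were called down in both panels (22 of 23 each). Of the glycolysis genes, 17 of 23 were called down in NEP, and 13 were called up and 6 down in ME, where the list did not pass (camera adjusted p = 0.137).

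NEP and ME were then compared directly, which sets the neural against the mesendodermal derivative. They also differed in duration (6 days and 36 h), in CHIR99021 dose (3 and 5 µM) and in DMH1 and SB431542, stated for NEP only. Lineage cannot be told apart from these conditions. Of the identity markers, SOX1, PAX6 and SOX2 were higher in NEP: SOX1 stood at 96.0 ± 3.15 against 2.52 ± 0.0307 CPM (log2 fold change 5.25, SE 0.0970, edgeR adjusted p = 3.21e-24), PAX6 at 9.50 ± 0.0563 CPM against 0 counts (at least 140-fold higher), and SOX2 at 397 ± 4.84 against 168 ± 1.19 CPM (log2 fold change 1.24, SE 0.0385, edgeR adjusted p = 1.71e-19). CRABP1, a retinoic acid binding protein, stood at 1113 ± 31.5 against 22.0 ± 1.42 CPM (log2 fold change 5.66, SE 0.0503, edgeR adjusted p = 2.03e-30). Primitive streak genes were lower in NEP, MIXL1 by a log2 fold change of -9.25 and TBXT of -8.99 (edgeR adjusted p = 2.85e-27 and 9.61e-27). CDH1 stood at 0.409 ± 0.0747 CPM in NEP and 362 ± 2.17 in ME (log2 fold change -9.77, SE 0.0901, edgeR adjusted p = 3.29e-30). In all, 5024 genes were higher and 5220 lower in NEP of 14710 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 1260 and 1911 differed by at least 2-fold.

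In this comparison, counts give list members higher or lower in NEP than in ME. Of the neuroepithelium genes 24 were higher and 7 lower of 34 (camera adjusted p = 0.000329, adjusted p = 0.168 with an estimated correlation). ZBTB16, a neural progenitor factor, stood at 43.8 ± 1.91 against 0.181 ± 0.128 CPM, TTYH1 at 58.1 ± 2.62 against 0.295 ± 0.0964, and GDF10, a TGF-beta family ligand, at 20.4 ± 2.07 CPM against 2 counts, while ZIC1 had 4 counts in NEP against 66.4 ± 3.43 CPM in ME. Of the hindbrain and HOX genes 19 were higher and 6 lower of 29 (camera adjusted p = 0.00364, adjusted p = 0.205 with an estimated correlation), HOXC8 with 3 counts in ME and a ratio of 434 (counting interval 148 to 2110), and with GBX2, an anterior hindbrain factor, lower at 17.0 ± 1.44 against 167 ± 4.53 CPM. Of the mesendoderm genes 20 were lower and 5 higher of 26 (camera adjusted p = 0.000136, adjusted p = 0.168 with an estimated correlation). EVX1 had 0 counts in NEP (at least 891-fold lower) and CDX1 stood at 0.153 ± 0.144 against 199 ± 1.78 CPM. FGF8 was higher. Of the definitive endoderm genes 12 were lower and 3 higher of 16 (camera adjusted p = 0.0191, adjusted p = 0.219 with an estimated correlation). Of the amnion and trophoblast genes 9 were lower and 0 higher of 10 (camera adjusted p = 0.00508, adjusted p = 0.44 with an estimated correlation). Of the surface ectoderm genes 13 were lower and 0 higher of 15 (camera adjusted p = 1.8e-06, adjusted p = 0.234 with an estimated correlation). KLKB1 (at least 208-fold lower), SOX14, an interneuron factor (at least 196-fold lower), and DLX5 (at least 139-fold lower) had 0 counts in NEP, and CACNA2D1, a calcium channel subunit, had 1, a ratio of ME to NEP of 1533 (counting interval 275 to 60600). Of the core pluripotency genes 22 were lower and 1 higher of 23 (camera adjusted p = 4.7e-09, adjusted p = 0.168 with an estimated correlation), POU5F1 with a log2 fold change of -7.90. Of the naive pluripotency genes 6 were lower and 0 higher of 9 (camera adjusted p = 0.00738, adjusted p = 0.215 with an estimated correlation). The remaining lineage lists were not called: anterior neural (2 were higher and 3 lower of 7, camera adjusted p = 0.799), neural crest (5 were higher and 10 lower of 20, camera adjusted p = 0.315) and neuron (10 were higher and 7 lower of 18, camera adjusted p = 0.56). Neither were paraxial (6 were higher and 9 lower of 19, camera adjusted p = 0.691), lateral and cardiac (2 were higher and 7 lower of 12, camera adjusted p = 0.0954), fibroblast (12 were higher and 15 lower of 31, camera adjusted p = 0.799) and endothelial (1 was higher and 1 lower of 9, camera adjusted p = 0.748).

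Of the WNT targets 18 were lower and 4 higher of 25 (camera adjusted p = 4.38e-05, adjusted p = 0.168 with an estimated correlation), with LGR5, a WNT co-receptor, among those higher in NEP. Of the NODAL and TGF-beta targets 15 were lower and 3 higher of 18 (camera adjusted p = 0.000145, adjusted p = 0.291 with an estimated correlation). Of the hedgehog genes 7 were higher and 3 lower of 11 (camera adjusted p = 0.0106, adjusted p = 0.291 with an estimated correlation), BOC, a hedgehog co-receptor, at 274 ± 5.49 against 2.88 ± 0.226 CPM. Of the epithelial adhesion genes 25 were lower and 0 higher of 26 (camera adjusted p = 1.78e-14, adjusted p = 0.168 with an estimated correlation). Of the glycolysis genes 19 were lower and 1 higher of 23 (camera adjusted p = 2.67e-08, adjusted p = 0.291 with an estimated correlation), LDHA at 162 ± 3.56 against 1184 ± 1.83 CPM. Of the HIF targets 14 were lower and 0 higher of 19 (camera adjusted p = 5.75e-05, adjusted p = 0.205 with an estimated correlation). Of the nuclear respiratory chain genes 26 were lower and 1 higher of 36 (camera adjusted p = 9.49e-05, adjusted p = 0.205 with an estimated correlation). Of the mitochondrially encoded genes 9 were lower and 0 higher of 13 (camera adjusted p = 0.00761, adjusted p = 0.519 with an estimated correlation). Of the p53 targets 18 were lower and 1 higher of 23 (camera adjusted p = 0.000157, adjusted p = 0.205 with an estimated correlation), CDKN1A at 34.6 ± 0.193 against 189 ± 0.791 CPM. Of the unfolded protein response genes 13 were lower and 3 higher of 18 (camera adjusted p = 0.00548, adjusted p = 0.31 with an estimated correlation). Of the ribosomal protein genes 44 were higher and 0 lower of 66 (camera adjusted p = 1.08e-10, adjusted p = 0.291 with an estimated correlation). Of the ribosome biogenesis genes 29 were lower and 8 higher of 45 (camera adjusted p = 0.00738, adjusted p = 0.219 with an estimated correlation). Of the interferon-stimulated genes 13 were lower and 2 higher of 19 (camera adjusted p = 0.00238, adjusted p = 0.215 with an estimated correlation). The FGF and ERK list was not called (11 were higher and 7 lower of 20, camera adjusted p = 0.433), although DUSP6 stood at 243 ± 0.970 against 15.8 ± 0.715 CPM (log2 fold change 3.95, SE 0.0555, edgeR adjusted p = 1.13e-26). Nor were the lists of BMP targets (5 were higher and 8 lower of 16, camera adjusted p = 0.296), retinoic acid targets (10 were higher and 8 lower of 20, camera adjusted p = 0.968) and NOTCH (7 were higher and 7 lower of 21, camera adjusted p = 0.605). Further lists not called were epithelial to mesenchymal transition (7 were higher and 6 lower of 15, camera adjusted p = 0.887), sterol synthesis (13 were higher and 6 lower of 25, camera adjusted p = 0.124), amino acid stress (7 were higher and 9 lower of 24, camera adjusted p = 0.303) and immediate early genes (7 were higher and 12 lower of 24, camera adjusted p = 0.315). The same held for DNA replication (10 were higher and 12 lower of 25, camera adjusted p = 0.703) and mitosis (9 were higher and 9 lower of 25, camera adjusted p = 0.968, or 9 and 10 with library-size scaling). It held also for histones (0 were higher and 6 lower of 10, camera adjusted p = 0.0954), RNA modification (9 were higher and 19 lower of 40, camera adjusted p = 0.315) and chromatin (9 were higher and 7 lower of 22, camera adjusted p = 0.703).

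Adjusted over the list alone, the counts in NEP against ME were the same as over all genes except for mesendoderm (21 lower), fibroblast (16 lower), hedgehog (8 higher), nuclear respiratory chain (28 lower) and mitosis genes (10 lower). Medians and means of the log2 fold change differed in sign for retinoic acid targets (0.05 and -0.20), epithelial to mesenchymal transition genes (-0.05 and 0.27), DNA replication genes (0.00 and -0.04) and chromatin genes (0.06 and -0.04). The anterior neural median was -2.07, or 0.17 with genes at 0 counts set to their bound. Genes at least 2-fold higher in NEP were enriched for nervous system development in the gene ontology (99 of 489, hypergeometric adjusted p = 2.37e-14), and those lower for immune response (57 of 159, adjusted p = 5.82e-10).

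Both derivatives were compared with the same hESC libraries, so the overlap of their changes was set beside simulations of unchanged groups. At 2-fold or more, 673 genes rose in both, 1165 fell in both and 127 went in opposite directions. The means over 20 simulations of unchanged groups were 0, 0 and 0.05 genes, and independent lists of these sizes would share 130.2, 265.1 and 371.9. Unchanged groups have few calls to share, so the simulated counts do not give the overlap of lists of these sizes by chance. The covariance of the log2 fold changes was 1.57 against 0.00729 in the simulations, and the correlation across genes, which are not independent replicates, was 0.641 against 0.139. The simulated groups were drawn around the observed hESC means, so the simulated values leave out the error that the shared libraries add to both comparisons. A split would leave 1 hESC library per comparison and was not made, so part of the excess may come from the shared controls. Of the genes that rose in both, 202 were at least 2-fold higher in NEP and 66 in ME, and of those that fell in both, 536 were lower in NEP and 33 in ME. The 127 opposite genes included MIXL1, the prohormone convertase PCSK1, at 3.66 CPM in hESC, 0.358 in NEP and 51.2 in ME, the bHLH factor HES2, at 1.60, 0.154 and 18.9, and the semaphorin SEMA6D, at 2.25, 18.2 and 0.204. SOX14 had 0 counts in NEP and 15.0 CPM in ME.

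HOX genes were also summed by paralogue group, which follows their order along the body axis. Of 39 HOX genes, 0 reached 10 CPM in hESC, 14 in NEP and 8 in ME, and the summed level was 1.65, 1387 and 401 CPM. Group 9 took 695 CPM in NEP and 18.0 in ME, whereas group 1 took 68.5 CPM in NEP and 235 in ME. HOXB9 alone made up 690.3 CPM of group 9 in NEP and 17.5 in ME. Groups 10 to 13 together reached 4.68 CPM in NEP and 3.70 in ME. These sums were described without a test.

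**Figure D3:**
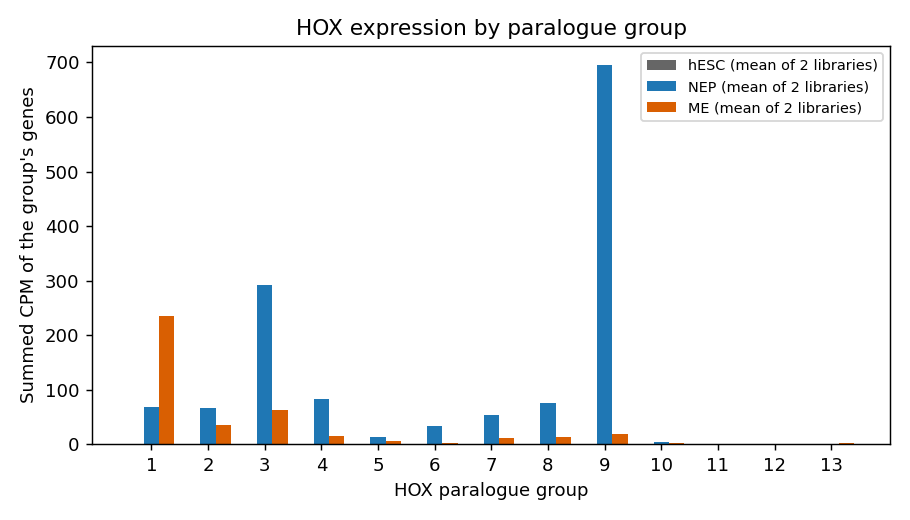
Summed level of the HOX genes of each paralogue group from 1 to 13, in CPM, as the mean of 2 libraries per group (grey, hESC; blue, NEP; orange, ME). Group 9 is the highest in NEP at 695 CPM, nearly all of it HOXB9, group 1 the highest in ME at 235 CPM, and the hESC bars are too low to be seen.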

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

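The alternative without genes of transcripts under 1000 bases was chosen only after the result was seen; under it all counts of called genes stayed within 1.5 times those reported, with for example 10763 genes called in NEP against hESC. Of the named genes' log2 fold changes, 0 reversed under any alternative run and 167 results lost their call, 132 of them in the test against a 2-fold change, which asks for more by construction. NR2F1 kept its call in NEP under all 18 alternatives, its log2 fold change running from 2.96 to 7.89 against hESC and from 2.95 to 11.79 against ME. The cause of the changes below was not tested unless stated. Depth limited what could be seen of genes near the floor of 0.130 to 0.154 CPM per library.

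The test against a 2-fold change called 1415 genes up and 2104 down in NEP against hESC, 682 and 929 in ME against hESC, and 783 and 1384 in NEP against ME, with 439, 748 and 55 genes up in both, down in both and opposite. The limma test on log2(FPKM + 1), where the added 1 shrinks changes of low genes, called 1133 up and 1516 down at 2-fold or more in NEP against hESC, 529 and 630 in ME against hESC, and 571 and 933 in NEP against ME, with 321, 525 and 30 in the overlap. Without a fold minimum, enriched KEGG pathways numbered 5 up and 31 down instead of 11 and 48 in NEP against hESC, 6 and 30 instead of 16 and 55 in ME against hESC, and 8 and 18 instead of 20 and 36 in NEP against ME. For NAT10 in NEP against hESC, the log2 fold change lost its call at -0.07 on log2(FPKM + 1), -0.072 on log2(FPKM + 0.1), -0.12 in the test against a 2-fold change, -0.09 without hESC replicate 1 and -0.096 without NEP replicate 2, the 6 fits with a library left out running from -0.157 to -0.09. It lost its call also in ME (0.18) and NEP against ME (-0.30) in the test against a 2-fold change.

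Leaving out a library left 1 library in its group, assumed to vary like the other groups. Adjusted p values of camera then ran from 0.0368 to 0.0718 for paraxial mesoderm in NEP against hESC, from 0.0415 to 0.108 for sterol genes and from 0.043 to 0.128 for definitive endoderm. In ME against hESC they ran from 0.00474 to 0.407 for mitochondrial genes, from 0.0499 to 0.0795 for paraxial mesoderm, from 4.28e-06 to 0.772 for ribosomal protein genes and from 0.0434 to 0.124 for endothelial genes. Library size alone gave 0.0626 for paraxial mesoderm in NEP against hESC and 0.0483 for ribosomal protein genes in ME against hESC, and DESeq2 size factors gave 0.039 for paraxial mesoderm in ME against hESC.

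With the replicate number as a block, 11494 genes instead of 11470 were called in NEP against hESC, 9351 instead of 9326 in ME against hESC and 10277 instead of 10244 in NEP against ME, and the paraxial mesoderm list in ME against hESC passed at 0.0443. It changed no other call of a list or a named gene, and no count of called genes by over 1.5 times. Samples of the same number did not deviate together (correlations of deviations across genes -0.03 for hESC and NEP, -0.04 for hESC and ME, and -0.01 for NEP and ME), so the numbers were not taken to pair the samples.

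With an estimated correlation, camera called 0 lists in each comparison, against 21, 12 and 21 with the preset value. In NEP against hESC, naive pluripotency, neuroepithelium, hindbrain and HOX, paraxial mesoderm and WNT had estimated correlations of -0.0163, -0.0208, 7e-04, -0.0441 and -0.0015. All of these lie under the preset 0.01 and all of these lists lost their call. For hindbrain and HOX, for example, the camera p before adjustment went from 9.61e-11 to 0.0054. A higher correlation between genes is thus argued against as the cause in these lists, and no other cause was tested. The loss of these calls is therefore no sign that they came from correlated genes. In the other lists called in NEP against hESC the estimate lay above the preset value. It was highest for mitochondrial (0.543), epithelial to mesenchymal transition (0.412), glycolysis (0.348), surface ectoderm (0.251), ribosomal protein (0.238) and NODAL (0.214). For such lists the preset 0.01 may be too low and the camera p too small. The fry test called 39, 30 and 36 lists. In NEP against hESC the adjusted p with an estimated correlation was 0.137 for core pluripotency, 0.207 for naive pluripotency, 0.137 for neuroepithelium, 0.137 for hindbrain and HOX, 0.313 for paraxial mesoderm, 0.313 for surface ectoderm and 0.141 for WNT. Further values were 0.313 for NODAL, 0.313 for retinoic acid, 0.313 for hedgehog, 0.429 for epithelial to mesenchymal transition, 0.137 for epithelial adhesion, 0.364 for glycolysis and 0.313 for HIF. Next came 0.295 for respiratory chain, 0.439 for mitochondrial, 0.364 for unfolded protein, 0.313 for DNA replication, 0.326 for ribosomal protein, 0.207 for ribosome biogenesis and 0.295 for interferon. For ME against hESC it was 0.101 for core pluripotency, 0.101 for hindbrain and HOX, 0.131 for mesendoderm, 0.101 for WNT, 0.464 for NODAL and 0.327 for retinoic acid. Further values were 0.382 for epithelial to mesenchymal transition, 0.327 for epithelial adhesion, 0.305 for sterol, 0.305 for p53, 0.284 for DNA replication and 0.305 for ribosome biogenesis. Between NEP and ME it was 0.168 for core pluripotency, 0.215 for naive pluripotency, 0.168 for neuroepithelium, 0.205 for hindbrain and HOX, 0.168 for mesendoderm, 0.219 for definitive endoderm and 0.44 for amnion and trophoblast. Further values were 0.234 for surface ectoderm, 0.168 for WNT, 0.291 for NODAL, 0.291 for hedgehog, 0.168 for epithelial adhesion, 0.291 for glycolysis and 0.205 for HIF. Next came 0.205 for respiratory chain, 0.519 for mitochondrial, 0.31 for unfolded protein, 0.205 for p53, 0.291 for ribosomal protein, 0.219 for ribosome biogenesis and 0.215 for interferon.

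Lists that passed in fry and not in camera had a fry adjusted p in NEP against hESC of 0.000282 for anterior neural, 0.000229 for neural crest, 0.000577 for neuron, 2.11e-05 for mesendoderm, 2.11e-05 for definitive endoderm and 5.84e-05 for lateral and cardiac mesoderm. Further values were 0.000219 for endothelial, 0.000375 for BMP, 2.11e-05 for FGF and ERK, 0.00542 for NOTCH, 0.00031 for sterol and 5.84e-05 for amino acid stress. Next came 0.000221 for immediate early, 0.00673 for p53, 0.0372 for mitosis, 0.00236 for histone and 0.00156 for RNA modification. In ME against hESC it was 0.000241 for naive pluripotency, 2.13e-05 for neuroepithelium, 0.000555 for anterior neural, 2.13e-05 for neural crest, 0.00238 for neuron, 0.00132 for definitive endoderm and 6.82e-06 for paraxial mesoderm. Further values were 0.00603 for lateral and cardiac mesoderm, 0.000267 for amnion and trophoblast, 0.0493 for fibroblast, 0.00085 for endothelial, 0.000234 for BMP, 8.09e-05 for FGF and ERK and 0.000721 for hedgehog. Next came 0.0145 for HIF, 0.00167 for amino acid stress, 0.0029 for immediate early, 0.0137 for RNA modification and 0.00035 for interferon. For NEP against ME the fry value was 0.0289 for anterior neural, 8.13e-05 for neural crest, 0.00893 for neuron, 7.08e-05 for lateral and cardiac mesoderm, 0.000665 for BMP, 0.00298 for FGF and ERK and 0.00737 for NOTCH. Further values were 0.0019 for sterol, 0.000205 for amino acid stress, 0.00201 for immediate early, 0.0164 for DNA replication, 0.00315 for histone and 0.00897 for RNA modification. The call lost in fry was in ME against hESC, with 0.136 for epithelial adhesion. The direction in fry was opposite to that of camera for amnion and trophoblast in NEP against hESC (0.00156) and for paraxial mesoderm (0.000285) and retinoic acid targets (0.00897) in NEP against ME.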

Other observations

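The tests of mitochondrial transcription, of reads shared among keratins and of the feeder share were chosen only after the result was seen, as were the genes of the next paragraph.

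Further genes moved in opposite directions in the 2 derivatives. IRX3, a neural tube patterning factor, stood at a mean of 3.28 CPM in hESC, 39.0 in NEP and 0.545 in ME, and SEMA3D, a guidance ligand, at 11.2, 56.1 and 1.77. The vesicle fusion gene VAMP8 stood at 13.9, 0.919 and 56.5 CPM, the epithelial trafficking gene RAB25 at 5.11, 0.843 and 19.5, and the protease receptor F2RL1 at 45.6, 10.1 and 150.4. Each was called in both comparisons with hESC (edgeR). Several regional markers had few counts anywhere: over the 6 libraries SIX3 had 5 counts, RAX 9 and LHX2 13, and among endoderm and organizer genes FOXA2 had 9 and GSC 28.

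The 2 hESC libraries differed in genes whose annotated transcripts are short. Outside mitochondrial and ribosomal protein genes, the median log2 ratio of replicate 2 to replicate 1 was 0.104 for 341 genes under 800 bases and -0.03 for 6809 genes over 2000 bases, a difference of 0.134, against 0.012 in NEP and 0.017 in ME. Better recovery of short transcripts in the library of hESC replicate 2 may be the source. The lengths are those of annotated genes, so recovery cannot be told apart here from the way reads were assigned to short genes. Higher mitochondrial transcription in hESC replicate 2 is argued against. Mitochondrial genes over 900 bases had a median log2 ratio of 0.015 and those under 400 bases 0.753, a quotient of 0.02. In ME against hESC, the ribosomal protein list went from 22 up and 24 down without hESC replicate 1 to 44 up and 1 down without hESC replicate 2, so part of its changes may be technical; no biological explanation was tested.

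KRT4 and KRT13, keratins of squamous epithelium, had 29 and 36 counts in ME replicate 1, 228 and 205 in ME replicate 2, and 0 in the other 4 libraries. Reads shared with KRT8, KRT18 and KRT19 are argued against, since hESC replicate 1, with the most of these (12133 counts), had 0 KRT4 and KRT13 counts. RNA of squamous cells in ME replicate 2 may be the source. The sum of 21 other markers, whose counts had not been seen, was 308 there against 112 in ME replicate 1. The ratio of 2.75 lay between the 1.5 and 3 set as bounds. The same markers summed to 59 and 36 counts in hESC and 61 and 41 in NEP. Part of both ME sums may thus be background that draws the ratio towards 1. TGM1 (24 against 19) and ECM1 (20 against 13) had counts in every library. SPRR3 (77 against 7), CRNN (47 against 7) and TGM3 (32 against 2) followed KRT4, while KRT14 (2 against 31), KRT6A (27 against 40) and KRT5 (33 against 29) did not. NEP replicate 1 also held KRT14 (15), KRT6A (10), S100A9 (9) and KRT5 (6), all at 0 in NEP replicate 2, and outside RNA and expression in the ME cells cannot be told apart.

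Fibroblast matrix genes differed between the groups: COL1A1 stood at 486 ± 25.7 CPM in hESC, 41.5 ± 4.98 in NEP and 132 ± 1.07 in ME, and COL1A2 at 124, 37.1 and 250.4. A smaller share of feeder fibroblast RNA in ME than in hESC may lower such genes, but would lower them together, and 50% of the called fibroblast genes fell in ME (13 of 26). The genes that rose argue against that share as the whole source of the differences in ME. For the genes that fell the test cannot decide, since feeder RNA or the cells themselves may lower them. The feeders were mouse cells and the genome build named is the human GRCh38. How far mouse reads were counted was not tested, nor was a biological explanation.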
